A study of Mus musculus with 22 samples.

How the data were processed

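RNA was measured in 22 libraries of sorted P14 CD8+ T cells from 7 sites: spleen (5), blood (4), small intestine epithelium (3), kidney (3), salivary gland (3), gonadal fat (2) and liver (2). Groups and replicate numbers were taken from the tissue labels and sample titles. Per the labels' protocols, cells from 10 to 15 mice were pooled for each replicate and 1000 resorted cells were lysed for a Smart-seq2 library. Whether libraries of different sites came from the same mice is not given in the sources used here, and the main test treats the 22 libraries as independent. Per the library labels, the libraries stand in 5 runs of wells. Every run held a spleen library, and no run repeated a site. Libraries of a run may thus have a shared origin, which the main test does not use. The run of wells as a block was tried as an alternative. Spleen and blood were processed without warm incubation, kidney, salivary gland, fat and liver were incubated with collagenase at 37 degrees, and the intestine was incubated at 37 degrees without collagenase, per the labels' protocols.

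The authors deposited raw counts per gene with Ensembl identifiers, 1 column per library, and those counts are the values tested here. The authors also deposited normalized signal values, which equal the raw counts divided by a single size factor per library plus 1; they served only to check that relation, and 2 columns of that table were not used because both carry the name of the same liver replicate. Trimmomatic 0.38, STAR 2.5.2b, featureCounts 1.5.3, DESeq2 1.3.2 and genome build mm10 are listed per the submitters' processing notes, with no role or order. The annotation, the strand setting and the treatment of reads with several hits are not given in the sources used here. Genes with close paralogs or antisense partners, such as Trgc1, Trgc2, the Trav segments, Ly6a2, Klra9, Apol9b and Mypopos, are therefore uncertain. Of 55401 features, 55141 identifiers matched GENCODE M21 regardless of version, which gave symbols and 1-based positions on GRCm38 (mm10). A symbol was shared by more than 1 feature in 110 cases. No pair of libraries was identical.

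Counts were tested in R 4.3.3 with edgeR 4.0.16: TMM normalization, filterByExpr (minimum count 10, minimum total 15) and the two-sided quasi-likelihood test in a single fit with 1 mean per site over all 22 libraries. All sites share an estimate of the spread in that fit, since fat and liver have 2 libraries each. Of 44227 features with a count, 12115 were tested. Benjamini-Hochberg adjusted p-values below 0.05 counted as past the threshold. The 12 comparisons were blood and each of the 5 tissues against spleen, the mean of the tissues against the mean of spleen and blood, and each tissue against the mean of the other 4. Genes past the threshold in the same direction in all 5 tissues against spleen were counted as shared. CPM use TMM library sizes, and principal components used log2 CPM with a prior count of 2. For a gene with 0 counts on the lower side, the fold is a bound with a floor of 3 counts over the group. With 1 to 3 counts on that side in a group, levels are given without a fold.

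A set of 30 gene lists with 497 symbols, all found in the table, was fixed before the data were examined. They cover residency-associated and circulation-associated genes, TGF-beta response, cytotoxic effectors, inhibitory receptors, trafficking and adhesion, transcription factors, retinoic acid and AHR, lipid uptake and oxidation, cholesterol biosynthesis, glycolysis, oxidative phosphorylation, interferon-stimulated, cell cycle, and immediate-early and heat-shock genes. Other lists hold markers of gut, kidney and salivary epithelium, adipocytes, hepatocytes, fibroblasts, endothelium, B cells, myeloid cells, erythroid cells and platelets, natural killer cells, CD4, gamma-delta and CD8 T cells, and sex-linked genes. Some genes stand in several lists, and residency, circulation and trafficking lists rest on general knowledge of such cells. Lists with at least 3 tested members were compared with other genes by camera in limma 3.58.1, with a preset correlation of 0.01 and adjustment over all lists and comparisons, and again with an estimated correlation.

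Named genes followed a rule fixed before the data were examined. For each comparison it takes the 8 genes higher and the 8 lower with the largest log2 fold changes among those past the threshold. These need at least 20 CPM on the higher side and libraries that do not overlap (against spleen) or that lie on one side of each other group's median (other comparisons). It adds up to 4 members past the threshold from each list, and 10 genes in each direction for the shared part. Predicted genes, names that are only identifiers, receptor segments and mitochondrial genes are left out, and a gene named in a comparison may be given in others. Some named genes are not reported here. Genes outside the rule are said to have been chosen after their values were seen.

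Depth ranged from 1410831 to 5899953 counts per library, and 15726 to 22434 features were detected. In tests on simulated counts with 200 changed genes, 2-fold changes against spleen were recovered for 46% of genes in blood, 40% in IEL, 34% in kidney, 46% in salivary gland, 20% in fat and 34% in liver. The shares for 4-fold changes were 77%, 75%, 86%, 84%, 69% and 74% in the same order. The alternatives tried were DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma voom with quality weights, no filter, a filter of 10 CPM in 2 libraries, replicate number, run of wells or plate as a block, leaving out the second plate, fits of 2 groups, a fold filter, blood as the control and each library left out in turn. Leaving out the 5 features with most counts, and leaving out fat 1 with salivary gland 2, were added after seeing the data. Other splits of the libraries and unchanged groups against the same spleen libraries were also run. The package data.table (version 1.17.8) read the input, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.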

Results

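The study profiled memory CD8+ T cells from several sites of the same infection, and its title asks how such cells differ between tissue environments. The cells were P14 cells, mouse CD8+ T cells with a transgenic receptor for a peptide of lymphocytic choriomeningitis virus (LCMV). They were sorted 32 days after infection with the Armstrong strain, an acute infection. The 22 libraries came from spleen (n = 5), blood (n = 4), the epithelium of the small intestine (IEL, intraepithelial lymphocytes, n = 3), kidney (n = 3), salivary gland (n = 3), gonadal fat (n = 2) and liver (n = 2). Each replicate was a pool of 10 to 15 mice, so the spread between libraries is a spread between pools. Vascular cells in the 5 tissues had been stained by an antibody given into the blood, and cells with low or no stain were sorted; no such gate was set for spleen and blood. Spleen, the site with the most libraries, was the reference for single tissues.

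Each library held between 1410831 and 5899953 counts. The totals were 2047756 to 5828573 in spleen, 1905562 to 3695587 in blood, 2370278 to 3213448 in IEL and 2041734 to 3546493 in kidney. They were 2250022 to 5556444 in salivary gland, 1410831 and 2655031 in fat, and 5899953 and 3591661 in liver. A ribosomal RNA feature (CT010467.1) and 4 predicted genes (Gm10800, Gm10801, Gm21738 and Gm10717) held a median of 41.22% of a library's counts, from 15.56% in liver 1 to 63.61% in fat 1. Library totals without molecular identifiers count reads, so bounds from a count of 0 cover counting error only. Levels are given as CPM (counts scaled to the library size), mean ± SD over the libraries of a group.

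Principal component 1 of the 500 most variable genes held 61.2% of their variance and component 2 held 11.6%. Spleen and blood libraries lay together: their mean correlation across genes was 0.909, against 0.912 within spleen and 0.937 within blood. IEL lay farthest from spleen (mean r = 0.354), followed by salivary gland (0.45), fat (0.614), kidney (0.637) and liver (0.649). Kidney correlated with fat at 0.861, with liver at 0.849 and with salivary gland at 0.847. These correlations run across genes, which are not independent replicates. Of the libraries, salivary gland 2 had the lowest mean rank correlation with the others (0.743). Spleen 1, salivary gland 1 and liver 1 came from a second plate, per the library labels. Each of those 3 libraries held 362 to 635 CPM of Xist, the RNA of the inactive X chromosome, and at most 0.13 CPM of each Y-linked gene. The other 19 held at most 6 CPM of Xist and expressed Y-linked genes. By these genes, cells on the 2 plates differed in sex. The second plate also had the deepest libraries, with 5556444 to 5899953 counts against at most 3695587. Plate, sex and depth therefore cannot be told apart, and leaving out the second plate changes all of them.

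**Figure D1:**
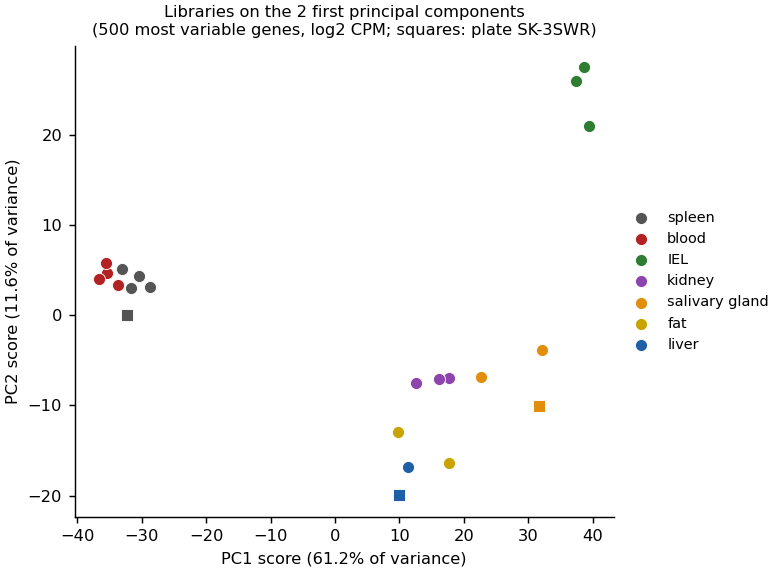
Principal components 1 and 2 of log2 CPM of the 500 most variable genes, 1 point per library and 1 colour per site, with squares for the 3 libraries of the second plate. Component 1 holds 61.2% and component 2 holds 11.6% of the variance, and the blood libraries, at -36.602 to -33.635 on component 1, lie next to the spleen libraries at -32.994 to -28.746.

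P14 cells from blood were close to those from spleen, and 5 genes differed. Klf6, an immediate-early zinc-finger factor, had 354 ± 85.2 CPM in blood (n = 4) and 138 ± 25.2 in spleen (n = 5). Zfp36, which encodes the RNA-binding protein tristetraprolin, fell from 56.6 ± 13.2 CPM in spleen to 20.2 ± 2.08 in blood. Inpp4b, a lipid phosphatase of the PI3K pathway, fell from 52.6 ± 8.04 to 26.4 ± 1.54 CPM. The log2 fold changes were 1.36 (SE 0.159) for Klf6 (adjusted p = 4.8e-05; ENSMUSG00000000078.7, chromosome 13, 5861482 to 5870394), -1.47 (SE 0.22) for Zfp36 (adjusted p = 0.00109; ENSMUSG00000044786.6, chromosome 7, 28376784 to 28380253) and -0.98 (SE 0.139) for Inpp4b (adjusted p = 0.000633; ENSMUSG00000037940.17, chromosome 8, 81342556 to 82127914). All 4 blood libraries lay on one side of all 5 spleen libraries for these 3 genes and for Nhsl2, which had 119 ± 16.6 CPM against 55.4 ± 15.3 (log2 fold change 1.10, adjusted p = 0.0459). The Nhsl2 call was lost without spleen 2 (adjusted p = 0.137), spleen 3 (0.0719), spleen 5 (0.166), blood 1 (0.117), blood 2 (0.11), blood 3 (0.272), IEL 1 (0.053) or kidney 3 (0.0528). Asb2, part of a ubiquitin ligase, was named only after its values were seen. It had 8.64 ± 2.92 CPM in spleen and 0.424 ± 0.427 in blood (adjusted p = 0.000272).

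These 5 genes, 2 higher and 3 lower in blood, were the calls among 12115 tested, and 803 genes had an unadjusted p below 0.05. Among 19 interferon-stimulated genes, 0 were higher and 0 lower (median log2 fold change -0.41, camera adjusted p = 2.06e-05). That list call held with an estimated correlation (adjusted p = 0.0229). Among 20 cytotoxic effector genes, 0 were higher and 0 lower (median log2 fold change 0.24, camera adjusted p = 4.37e-05, but adjusted p = 0.14 with an estimated correlation). Among 22 circulation-associated genes, 0 were higher and 0 lower (median log2 fold change 0.13, camera adjusted p = 0.0212, but adjusted p = 0.219 with an estimated correlation). Among 26 residency-associated genes, 0 were higher and 1 lower (median log2 fold change -0.10, camera adjusted p = 0.879). Among 4 natural killer cell markers, the receptor genes Klrb1c and Klra9 and the adaptor genes Tyrobp and Fcer1g, which myeloid cells share, 0 were higher and 0 lower (median log2 fold change 0.68, camera adjusted p = 0.00547, but adjusted p = 0.0591 with an estimated correlation). In blood, the counts of higher and lower genes adjusted over the list alone were the same except 0 and 4 for interferon-stimulated genes, 5 and 0 for cytotoxic effectors, 5 and 2 for circulation, 4 and 3 for residency and 1 and 0 for natural killer markers. The count of 5 was 11 without spleen 1, 8 without spleen 4, 18 without blood 4 and 11 without salivary gland 2, while DESeq2 called 44 genes and limma voom 12. It was 41 with the run of wells and 16 with the plate in the fit, 78 without a filter, 21 without the second plate, 16 in a fit of the 2 groups alone and 11 without fat 1 and salivary gland 2, a setting chosen after seeing the data. Tests on simulated counts recovered 46% of genes changed 2-fold and 77% of those changed 4-fold for this comparison.

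P14 cells from the intestinal epithelium expressed the integrin gene Itgae (CD103) at 572 ± 87.5 CPM (n = 3) against 5.83 ± 2.45 in spleen, a fitted fold of 101. The gut-homing receptor gene Ccr9 was at 293 ± 14.8 CPM against 8.55 ± 3.09, a fitted fold of 35.4. Nuclear receptor genes induced by antigen receptor signals were higher still, with Nr4a1 at 2390 ± 314 CPM against 5.56 ± 2.22 and Nr4a2 at 838 ± 82.9 against 1.23 ± 0.429. In the opposite direction, the chemokine receptor gene Cx3cr1 fell from 314 ± 93.9 CPM to 0.84 ± 0.347. The egress receptor gene S1pr5 had 0 counts in all 3 IEL libraries, at least 410-fold lower than its 157 ± 40.2 CPM in spleen. The log2 fold change of Itgae was 6.65 (SE 0.353) (adjusted p = 4.01e-14; ENSMUSG00000005947.11, chromosome 11, 73090583 to 73147446) and that of Ccr9 5.14 (SE 0.334) (adjusted p = 1.73e-12; ENSMUSG00000029530.16, chromosome 9, 123678439 to 123784330). Nr4a1 changed by 8.88 (SE 0.359) (adjusted p = 1.34e-16; ENSMUSG00000023034.7, chromosome 15, 101254269 to 101274795) and Cx3cr1 by -8.40 (SE 0.426) (adjusted p = 1.68e-14; ENSMUSG00000052336.7, chromosome 9, 119901616 to 120069879). Positions are those of build mm10 (GRCm38). Unless said otherwise, for each gene given with a log2 fold change against spleen, all libraries of the tissue lay on one side of all 5 spleen libraries.

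All 26 residency-associated genes tested rose in IEL, with a median log2 fold change of 4.17 (camera adjusted p = 2.41e-39). Nr4a1 stands both in this list and in the immediate-early and heat-shock list. Each tissue had a warm incubation, and spleen and blood had none. For residency list calls against spleen or circulation, in IEL and the other tissues, handling and tissue of origin therefore cannot be told apart. The residency list was not retested with any member left out. Rgs1, a brake on G protein signals, rose by 6.25 and the adhesion gene Cdh1 by 5.37 (6.02 without spleen 1). Among 22 circulation-associated genes, 0 were higher and 21 lower (median log2 fold change -2.77, camera adjusted p = 4.4e-23). The egress receptor gene S1pr1 changed by -6.30. Among 11 TGF-beta response genes, 10 were higher and 0 lower (median log2 fold change 3.01, camera adjusted p = 3.85e-12), and the corepressor gene Tgif1 rose by 3.82. Among 14 inhibitory receptor genes, 13 were higher and 1 lower (median log2 fold change 2.46, camera adjusted p = 4.38e-14). Ctla4 rose from 10.2 ± 4.52 to 301 ± 67.1 CPM, Tigit from 23.7 ± 9.18 to 420 ± 59.8 and Pdcd1, which encodes PD-1, from 12 ± 2.4 to 201 ± 48.3.

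Among 24 genes of cholesterol synthesis and uptake, 21 were higher and 0 lower (median log2 fold change 1.94, camera adjusted p = 1.08e-15). The sterol demethylase gene Cyp51 had a log2 fold change of 3.92 and the sterol sensor gene Insig1 3.90. Dgat1, which makes storage triglycerides, rose from 15.4 ± 4.73 to 373 ± 52.3 CPM. Cytotoxic effector genes went both ways: of 20, 12 were higher and 3 lower (camera adjusted p = 1.35e-07, but adjusted p = 0.0637 with an estimated correlation). The chemokine genes Ccl3 and Ccl4 rose by 4.10 and 3.93, while granzyme M (Gzmm) fell from 82.3 ± 12.9 to 3.88 ± 4.58 CPM and the activating receptor gene Klrk1 from 447 ± 44.2 to 27.8 ± 6.56. Among 27 immediate-early and heat-shock genes, 25 were higher and 1 lower (median log2 fold change 3.33, camera adjusted p = 6.13e-24), with Egr1 at 542 ± 139 CPM against 9.24 ± 4.15. Among 30 transcription factor genes, 16 were higher and 7 lower (camera adjusted p = 0.000341). Hic1, a repressor induced by retinoic acid, rose by 5.01, and the aryl hydrocarbon receptor gene Ahr from 0.615 ± 0.622 to 18.3 ± 2.62 CPM (log2 fold change 4.86 (SE 0.642)).

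Among 22 trafficking genes, 4 were higher and 12 lower (camera adjusted p = 0.0376, but adjusted p = 0.211 with an estimated correlation and 0.0552 with the plate in the fit). The next 6 lists did not pass. Of 8 retinoic acid and AHR genes, 4 were higher and 3 lower (camera adjusted p = 0.116), and of 17 genes of lipid uptake and oxidation, 6 were higher and 1 lower (camera adjusted p = 0.052). Of 18 glycolysis genes, 2 were higher and 2 lower (camera adjusted p = 0.806), and of 26 oxidative phosphorylation genes, 1 was higher and 1 lower (camera adjusted p = 0.399). Of 19 interferon-stimulated genes, 6 were higher and 2 lower (camera adjusted p = 0.054), and of 22 cell cycle genes, 0 were higher and 2 lower (camera adjusted p = 0.122). Of the markers of other cells, 5 from gut epithelium were tested, of which 3 were higher and 0 lower (camera adjusted p = 0.0246, but adjusted p = 0.14 with an estimated correlation). Their summed level was 51 ± 13.5 CPM in IEL and 17 ± 7.98 in spleen. Among 4 gamma-delta T cell genes, 2 were higher and 0 lower (camera adjusted p = 0.0408, but adjusted p = 0.214 with an estimated correlation, 0.075 with the run of wells and 0.0595 with the plate in the fit), the 2 being the constant-segment genes Trgc1 and Trgc2, which have close paralogs and are uncertain. In IEL, counts adjusted over the list alone were the same except 13 and 3 for cytotoxic effectors, 5 and 13 for trafficking, 3 and 2 for glycolysis, 7 and 2 for interferon-stimulated genes, 4 and 1 for gut epithelium and 3 and 0 for gamma-delta T cells. In all, 1458 genes were higher and 1224 lower in IEL, 2682 of 12115.

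P14 cells from kidney expressed more of the chemokine gene Xcl1, with 54.5 ± 19.2 CPM (n = 3) against 1.96 ± 0.578 in spleen, a log2 fold change of 4.76 (SE 0.317) (adjusted p = 1.23e-11). They also had more of the chemokine genes Ccl3 (185 ± 37.2 against 10.2 ± 1.79 CPM) and Ccl4 (log2 fold change 3.88). Interferon gamma (Ifng) was at 111 ± 28.9 against 7.19 ± 2.34 CPM and Tnf at 124 ± 8.34 against 6.57 ± 2. Nr4a1 reached 1210 ± 462 CPM (log2 fold change 7.90 (SE 0.349), adjusted p = 2.83e-15). Itgae, at 7.97 ± 3.69 CPM, did not pass the test (adjusted p = 0.691), while the integrin gene Itga1 (CD49a) rose to 154 ± 20.4 CPM from 43.4 ± 2.64. Cx3cr1 changed by -2.83 (SE 0.263) (adjusted p = 6.14e-09) and S1pr5 by -3.31 (SE 0.276) (adjusted p = 5.32e-09; ENSMUSG00000045087.8, chromosome 9, 21242912 to 21248443).

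Among 26 residency-associated genes, 22 were higher and 0 lower (median log2 fold change 2.78, camera adjusted p = 8.2e-37). Among 22 circulation-associated genes, 0 were higher and 15 lower (median log2 fold change -1.62, camera adjusted p = 9.72e-24). Among 27 immediate-early and heat-shock genes, 24 were higher and 1 lower (median log2 fold change 3.14, camera adjusted p = 2.49e-40), including Fos at 758 ± 40.1 CPM against 15.6 ± 10. Among 14 inhibitory receptor genes, 7 were higher and 1 lower (camera adjusted p = 2.55e-06), with Tigit at 3.23 and Pdcd1 at 3.18. Among 19 interferon-stimulated genes, 7 were higher and 0 lower (camera adjusted p = 6.93e-06), with the ubiquitin-like Isg15 at 1.66. Among 30 transcription factor genes, 11 were higher and 3 lower (camera adjusted p = 7.82e-05), and Irf4 rose from 3.76 ± 2.19 to 74.9 ± 11 CPM. Among 20 cytotoxic effector genes, 11 were higher and 4 lower (camera adjusted p = 1.43e-07, but adjusted p = 0.0635 with an estimated correlation). Among 11 TGF-beta response genes, 5 were higher and 0 lower (camera adjusted p = 5.07e-05, but adjusted p = 0.1 with an estimated correlation). Among 18 glycolysis genes, 5 were higher and 0 lower (camera adjusted p = 0.002, but adjusted p = 0.175 with an estimated correlation).

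Kidney had 764 genes higher and 417 lower. Among 7 B cell markers, 5 were higher and 0 lower (camera adjusted p = 0.00805, but adjusted p = 0.219 with an estimated correlation). They were led by H2-Ab1 (log2 fold change 4.76 (SE 0.86)) and Cd74 (3.43), or 3.06 and 2.36 without kidney 3, both genes of MHC class II presentation that B cells share with macrophages and dendritic cells. The summed level of 4 class II genes was 28.2, 26.4 and 153.8 CPM in kidney 1, 2 and 3 and at most 9.3 CPM in each of the 16 libraries outside kidney and salivary gland. Without kidney 3, H2-Aa (adjusted p = 0.216) and H2-Eb1 (0.108) no longer passed. In kidney, counts adjusted over the list alone were the same except 26 and 1 for immediate-early and heat-shock genes, 8 and 1 for inhibitory receptors, 10 and 0 for interferon-stimulated genes, 14 and 3 for transcription factors, 12 and 5 for cytotoxic effectors, 7 and 0 for the TGF-beta response, 7 and 0 for glycolysis and 5 and 1 for B cell markers.

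P14 cells from salivary gland combined high Cdh1, which encodes the adhesion protein E-cadherin, with little granzyme A. Cdh1 had 200 ± 86.7 CPM (n = 3) against 2.29 ± 1.56 in spleen (log2 fold change 6.30 (SE 0.404), adjusted p = 2.87e-12; ENSMUSG00000000303.12, chromosome 8, 106603351 to 106670246), or 6.94 without spleen 1. Itgae had 168 ± 104 CPM (4.90 (SE 0.343), adjusted p = 1.36e-11), or 4.25 without salivary gland 1. Xcl1 reached 159 ± 35.1 CPM (6.30 (SE 0.311), adjusted p = 2.23e-14; ENSMUSG00000026573.7, chromosome 1, 164931644 to 164935527) and the hair keratin gene Krt83 158 ± 72.9 CPM (7.55 (SE 0.569)). Gzma fell from 415 ± 165 to 14.6 ± 7.76 CPM (-4.89 (SE 0.469), adjusted p = 5.71e-09; ENSMUSG00000023132.8, chromosome 13, 113093825 to 113100981). The natural killer receptor gene Klrb1c fell from 79.7 ± 21.8 to 2.71 ± 1.43 CPM. S1pr5 had 0 counts in the 3 libraries, at least 626-fold lower than in spleen.

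Among 26 residency-associated genes, 25 were higher and 0 lower (median log2 fold change 3.51, camera adjusted p = 1.09e-36). Among 11 TGF-beta response genes, 10 were higher and 0 lower (median log2 fold change 3.58, camera adjusted p = 1.86e-14). Skil and Pmepa1, feedback inhibitors of TGF-beta signals, rose by 3.97 and 7.01, the latter 7.87 without spleen 1. Among 22 circulation-associated genes, 0 were higher and 17 lower (median log2 fold change -2.15, camera adjusted p = 3.54e-23). Among 20 cytotoxic effector genes, 10 were higher and 6 lower (camera adjusted p = 0.0198, but adjusted p = 0.355 with an estimated correlation and 0.0581 with the replicate block): Ifng (3.42) and Tnf (3.62) rose while Gzma and Gzmm (-3.53) fell. Among 14 inhibitory receptor genes, 9 were higher and 0 lower (camera adjusted p = 4.48e-08), with Pdcd1 at 219 ± 100 CPM against 12 ± 2.4. Among 27 immediate-early and heat-shock genes, 25 were higher and 1 lower (median log2 fold change 2.75, camera adjusted p = 2.6e-25). Among 24 cholesterol genes, 9 were higher and 0 lower (camera adjusted p = 0.00111, but adjusted p = 0.0907 with an estimated correlation), with Cyp51 at 2.58. Among 19 interferon-stimulated genes, 6 were higher and 0 lower (camera adjusted p = 0.00656, but adjusted p = 0.131 with an estimated correlation). Among 30 transcription factor genes, 13 were higher and 5 lower (camera adjusted p = 0.00337, but adjusted p = 0.0897 with an estimated correlation), with Irf4 at 5.16.

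Salivary gland had 1218 genes higher and 852 lower than spleen. Both tested hepatocyte markers, Trf and Apoa1, were higher, and this rested on salivary gland 2. Apoa1 was at 43.43 CPM in it and 0 in the other 2 libraries. Without it Trf had a log2 fold change of 1.62 (adjusted p = 0.315), and without it and fat 1, a setting chosen after seeing the data, Apoa1 had -2.87. The sum of 18 hepatocyte genes was 636.6 CPM in salivary gland 2 and at most 22.5 CPM in each other library. Among 3 salivary epithelium markers, 0 were higher and 0 lower (camera adjusted p = 0.964). Among 5 gut epithelium markers, 3 were higher and 0 lower (camera adjusted p = 0.574), and the summed level was 113.3 CPM in salivary gland 2 beside 17.9 and 18.8 in the other 2 libraries. Without salivary gland 2, Epcam (1.712, adjusted p = 0.12) and Fabp1 (-1.293, adjusted p = 0.684) no longer passed. Among 8 myeloid markers, 3 were higher and 0 lower (camera adjusted p = 0.095). The class II sum was 23.5, 42.9 and 248.2 CPM in salivary gland 1, 2 and 3. In salivary gland, counts adjusted over the list alone were the same except 0 and 18 for circulation, 12 and 1 for inhibitory receptors, 26 and 1 for immediate-early and heat-shock genes, 10 and 0 for cholesterol genes, 14 and 5 for transcription factors and 1 and 0 for salivary epithelium.

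P14 cells from fat had more of Rgs2, a regulator of G protein signals, at 280 ± 87.4 CPM (n = 2) against 5.67 ± 2.34 in spleen (log2 fold change 5.77 (SE 0.313), adjusted p = 3.28e-13). The chemokine receptor gene Cxcr4 was at 112 ± 4.46 CPM against 12.4 ± 8.41 (3.17 (SE 0.348), adjusted p = 1.65e-07; ENSMUSG00000045382.6, chromosome 1, 128588199 to 128592293). Nr4a1 had 1310 ± 229 CPM (8.01 (SE 0.361), adjusted p = 8.7e-15). The salt-inducible kinase gene Sik1 rose by 5.62, the NF-kappa-B inhibitor gene Tnfaip3 by 3.95 and the granzyme B inhibitor gene Serpinb9 by 2.95. S1pr5 changed by -6.38 (SE 0.488) (adjusted p = 1.68e-09), Cx3cr1 by -5.01, the Notch regulator gene Dtx1 by -4.83 and Gzma by -2.98; without fat 2, S1pr5 had -7.02 and Gzma -4.45. Itgae, at 6.44 ± 0.619 CPM, did not pass the test (adjusted p = 0.854).

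Among 26 residency-associated genes, 16 were higher and 0 lower (median log2 fold change 2.18, camera adjusted p = 5.4e-18). Among 22 circulation-associated genes, 1 was higher and 15 lower (median log2 fold change -1.48, camera adjusted p = 2.92e-13). Among 27 immediate-early and heat-shock genes, 23 were higher and 1 lower (camera adjusted p = 8.53e-28). Among 18 glycolysis genes, 6 were higher and 0 lower (camera adjusted p = 4.71e-05, but adjusted p = 0.082 with an estimated correlation), with the hexokinase gene Hk2 at 2.40 and the hypoxia factor gene Hif1a at 1.60. Among 26 oxidative phosphorylation genes, 6 were higher and 0 lower (camera adjusted p = 0.000329, but adjusted p = 0.219 with an estimated correlation). Among 20 cytotoxic effector genes, 9 were higher and 3 lower (camera adjusted p = 0.000426, but adjusted p = 0.204 with an estimated correlation), with Ifng at 72 ± 1.68 CPM. Among 14 inhibitory receptor genes, 6 were higher and 1 lower (camera adjusted p = 0.00264, but adjusted p = 0.139 with an estimated correlation), with Ctla4 at 3.50 (2.82 without fat 2). Among 30 transcription factor genes, 10 were higher and 3 lower (camera adjusted p = 0.00149, but adjusted p = 0.0676 with an estimated correlation). Among 24 cholesterol genes, 3 were higher and 0 lower (camera adjusted p = 0.0291, but adjusted p = 0.237 with an estimated correlation). Among 22 cell cycle genes, 1 was higher and 0 lower (camera adjusted p = 0.00615, but adjusted p = 0.281 with an estimated correlation). Interferon-stimulated genes did not pass as a list: of 19, 2 were higher and 0 lower (camera adjusted p = 0.834). The single tested adipocyte marker, Plin4, did not pass the test (1.715 CPM against 3.331, adjusted p = 0.466). In fat, counts adjusted over the list alone were the same except 18 and 0 for residency, 1 and 17 for circulation, 24 and 1 for immediate-early and heat-shock genes, 7 and 0 for glycolysis, 9 and 5 for cytotoxic effectors, 7 and 2 for inhibitory receptors and 11 and 4 for transcription factors. Fat had 870 genes higher and 517 lower, and without fat 1, which left 1 library, 606 genes passed in place of 1387 (610 without salivary gland 2 as well).

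P14 cells from liver expressed the interferon-induced chemokine gene Cxcl10 at 116 ± 0.16 CPM (n = 2) against 0.291 ± 0.527 in spleen (log2 fold change 8.41 (SE 0.515), adjusted p = 1.02e-11; ENSMUSG00000034855.13, chromosome 5, 92346638 to 92348889), or 9.55 without spleen 2. Ifng reached 297 ± 44.9 CPM (5.45 (SE 0.303), adjusted p = 3.64e-13), and the interleukin 2 receptor gene Il2ra 167 ± 25.3 CPM (3.24 (SE 0.259), adjusted p = 2.73e-10; ENSMUSG00000026770.5, chromosome 2, 11642807 to 11693193). The glycolytic enzyme gene Hk2 rose to 67 ± 10.5 CPM from 3.51 ± 0.85 (4.26 (SE 0.342), adjusted p = 2.9e-10; ENSMUSG00000000628.10, chromosome 6, 82725025 to 82774454). The lymph node homing receptor gene Ccr7 rose to 378 ± 101 CPM from 72.9 ± 25.1 (2.36 (SE 0.398), adjusted p = 9.3e-05; ENSMUSG00000037944.8, chromosome 11, 99144196 to 99155077). Nr4a1 had 1890 ± 767 CPM (8.54). Lower genes included Cx3cr1 (-2.49), S1pr5 (-3.44) and the potassium channel gene Kcnj8 (-2.76).

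Among 19 interferon-stimulated genes, 18 were higher and 0 lower (median log2 fold change 1.37, camera adjusted p = 1.94e-20), with Ifit1 at 95.1 ± 33.2 CPM against 12.5 ± 4.63 and Rsad2 at 4.21. Among 18 glycolysis genes, 15 were higher and 0 lower (median log2 fold change 1.18, camera adjusted p = 7.85e-16), with the isomerase gene Tpi1 at 2.25. Of 26 residency-associated genes, 17 were higher and 0 lower (median log2 fold change 2.46, camera adjusted p = 4.5e-17). Of 22 circulation-associated genes, 1 was higher and 11 lower (median log2 fold change -0.85, camera adjusted p = 5.16e-07), the higher one being Ccr7. Among 20 cytotoxic effector genes, 10 were higher and 0 lower (camera adjusted p = 8.14e-09). Among 14 inhibitory receptor genes, 5 were higher and 0 lower (camera adjusted p = 8.23e-05, but adjusted p = 0.0586 with an estimated correlation). Of 30 transcription factor genes, 10 were higher and 1 lower (camera adjusted p = 3.77e-06). Among 27 immediate-early and heat-shock genes, 26 were higher and 0 lower (camera adjusted p = 2.51e-31). Among 11 TGF-beta response genes, 6 were higher and 0 lower (camera adjusted p = 0.00145, but adjusted p = 0.186 with an estimated correlation). Itgae was at 19.3 ± 11.7 CPM, with a call (log2 fold change 1.83) that ended without liver 1 (0.95, adjusted p = 0.368). The 2 tested hepatocyte markers did not pass. In liver, counts adjusted over the list alone were the same except 19 and 0 for interferon-stimulated genes, 1 and 13 for circulation, 11 and 0 for cytotoxic effectors, 13 and 1 for transcription factors and 6 and 1 for the TGF-beta response. Liver had 1071 genes higher and 615 lower, and without liver 1, the liver library of the second plate, 809 genes passed in place of 1686.

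**Figure D2:**
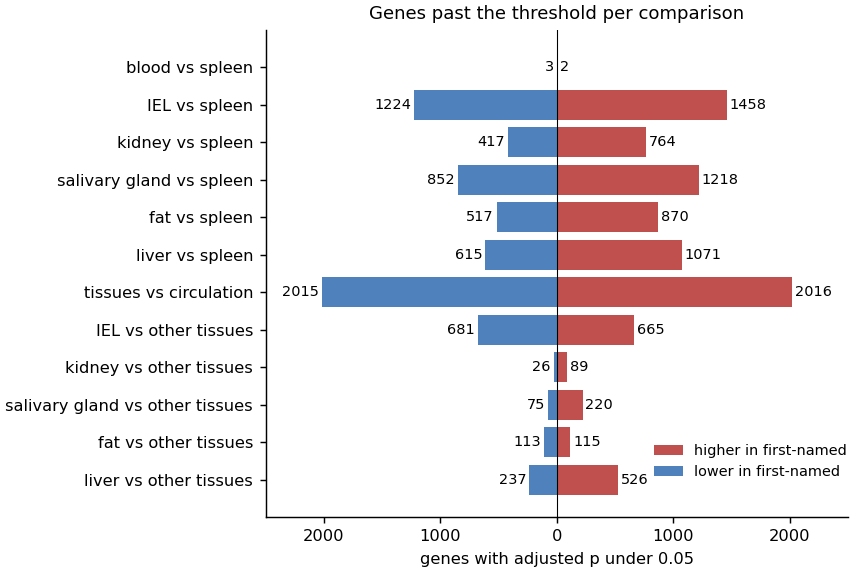
Bars count the genes with adjusted p under 0.05 (horizontal axis, number of genes) in each of the 12 comparisons, to the right when higher and to the left when lower in the group named first. Blood against spleen gave 5 genes and tissues against circulation 4031.

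**Figure D3:**
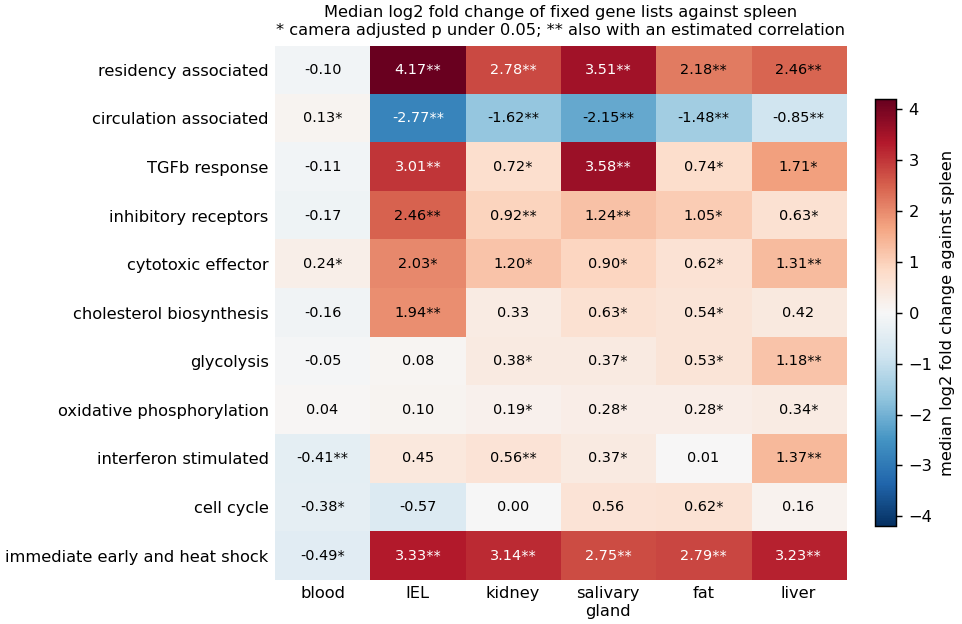
Cells show the median fitted log2 fold change of 11 fixed gene lists (vertical axis) in blood and each tissue against spleen (horizontal axis), red for higher and blue for lower. A star marks camera adjusted p under 0.05 and a pair of stars that it also holds with an estimated correlation; immediate-early and heat-shock genes reach 2.75 or more in each tissue, and with low-count genes set at their bounds their median in blood is -0.42.

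The 5 tissues shared 356 genes higher and 95 lower than spleen. All 5 were also incubated at 37 degrees and spleen was not, so handling and tissue of origin cannot be told apart for these genes. The nuclear receptor genes Nr4a1, Nr4a2 and Nr4a3 rose by at least 7.77, 7.16 and 5.57 on the log2 scale in each tissue, the cell cycle inhibitor gene Cdkn1a by at least 5.51 and Sik1 by at least 4.70. The stress factor gene Atf3 had 0 counts in spleen and was at least 40-fold higher in IEL, 37.4-fold in kidney, 89.2-fold in salivary gland, 90.3-fold in fat and 152-fold in liver. Ramp3, part of receptors for calcitonin-family peptides, was named among the shared genes along with Calca, which encodes calcitonin and its gene-related peptide; Ramp3 was at least 59.9-fold higher in IEL, 31.7-fold in kidney, 59.7-fold in salivary gland, 72.7-fold in fat and 93.5-fold in liver. On the lower side, Cx3cr1 fell by at least 2.49 on the log2 scale, and Arhgef18 by 1.73 to 2.79 from 297 ± 15.2 CPM in spleen.

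Changes against spleen correlated between tissues, from 0.534 for IEL with liver to 0.769 for kidney with salivary gland, across genes that are not independent replicates. Comparisons with the same spleen libraries share the chance values of those libraries. With 20 simulations of unchanged tissues against those libraries, 0 genes were called in all 5, and independent lists would share 0.059 higher and 0.0064 lower genes. No simulated test called more than 1 gene, so 0 in all 5 was nearly fixed in advance. The simulated tissues were drawn around the mean of the same spleen libraries, which leaves out chance deviations of that mean. The simulations therefore do not measure what the common spleen libraries add to the overlap. They also do not cover a handling effect common to the 5 tissues. With spleen 1 and 2 as the reference for IEL and salivary gland and spleen 3 to 5 for kidney, fat and liver, 256 genes were higher and 56 lower. The mean correlation was 0.647 against 0.117 in the simulations; over the 6 pairs of tissues that the split separates, it was 0.643 with all spleen libraries and 0.532 with the split. The mean covariance was 0.723 against 0.026, a difference of 0.697. Neither simulated value includes chance deviations of the spleen mean, so the gaps to 0.117 and 0.026 are not corrected for the common libraries. The shared lower count was 50 without fat 1, 61 without liver 1 and 54 without fat 1 and salivary gland 2. On the main plate alone, 296 genes were higher and 53 lower in all 5 tissues, and the comparisons with spleen gave 2604 genes in IEL, 1140 in kidney, 1411 in salivary gland, 1288 in fat and 827 in liver; the second plate held 1 library each of spleen, salivary gland and liver, too few for a test of its own.

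Against circulation as a whole, the mean of spleen and blood, the mean of the 5 tissues had 2016 genes higher and 2015 lower. In these contrasts of means, CPM are means of group means and the log2 fold change compares means of log2 levels. Nr4a1 was at 1580 CPM in tissues (13 libraries) and 4.65 in circulation (9 libraries), with a log2 fold change of 8.47 (SE 0.265) (adjusted p = 7.18e-19). Cx3cr1 was at 24.2 against 453 CPM (-5.18 (SE 0.172), adjusted p = 1.57e-18). All 13 tissue libraries lay above, or for Cx3cr1 below, all 9 from spleen and blood. Xcl1 (5.70), Rgs1 (5.00), Tigit (3.44) and Ifng (3.62) were higher, and Kcnj8 (-3.48), Klrb1c (-2.85) and Cmah (-2.84) were lower.

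By list, tissues differed from circulation in residency-associated genes, of which 24 were higher and 0 lower (camera adjusted p = 4.02e-27), and in circulation-associated genes, of which 0 were higher and 20 lower (camera adjusted p = 4.8e-23). Of the 11 TGF-beta response genes, 10 were higher and 0 lower (camera adjusted p = 1.84e-07). Of the 14 inhibitory receptor genes, 12 were higher and 0 lower (camera adjusted p = 2.49e-08). Of the 24 cholesterol genes, 18 were higher and 0 lower (camera adjusted p = 8.19e-06), and of the 19 interferon-stimulated genes, 15 were higher and 0 lower (camera adjusted p = 8.04e-08). Of the 18 glycolysis genes, 12 were higher and 0 lower (camera adjusted p = 2.39e-06). Of the 26 oxidative phosphorylation genes, 11 were higher and 0 lower (camera adjusted p = 0.000853, but adjusted p = 0.248 with an estimated correlation). Of the 27 immediate-early and heat-shock genes, 25 were higher and 1 lower (camera adjusted p = 3.66e-25). Of the 4 natural killer cell markers, the receptor genes Klrb1c and Klra9 and the adaptor genes Tyrobp and Fcer1g, 0 were higher and 3 lower (camera adjusted p = 0.0174, but adjusted p = 0.114 with an estimated correlation). Of the 10 genes of CD8+ T cells themselves, 7 were higher and 1 lower (camera adjusted p = 0.000101, but adjusted p = 0.134 with an estimated correlation). Between tissues and circulation, counts adjusted over the list alone were the same except 18 and 1 for cholesterol genes, 17 and 0 for interferon-stimulated genes, 13 and 0 for glycolysis, 12 and 0 for oxidative phosphorylation and 1 and 3 for natural killer markers. Over the 288 list tests of all comparisons, 135 passed with the preset correlation and 57 with an estimated one, all 57 among the 135.

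**Figure D4:**
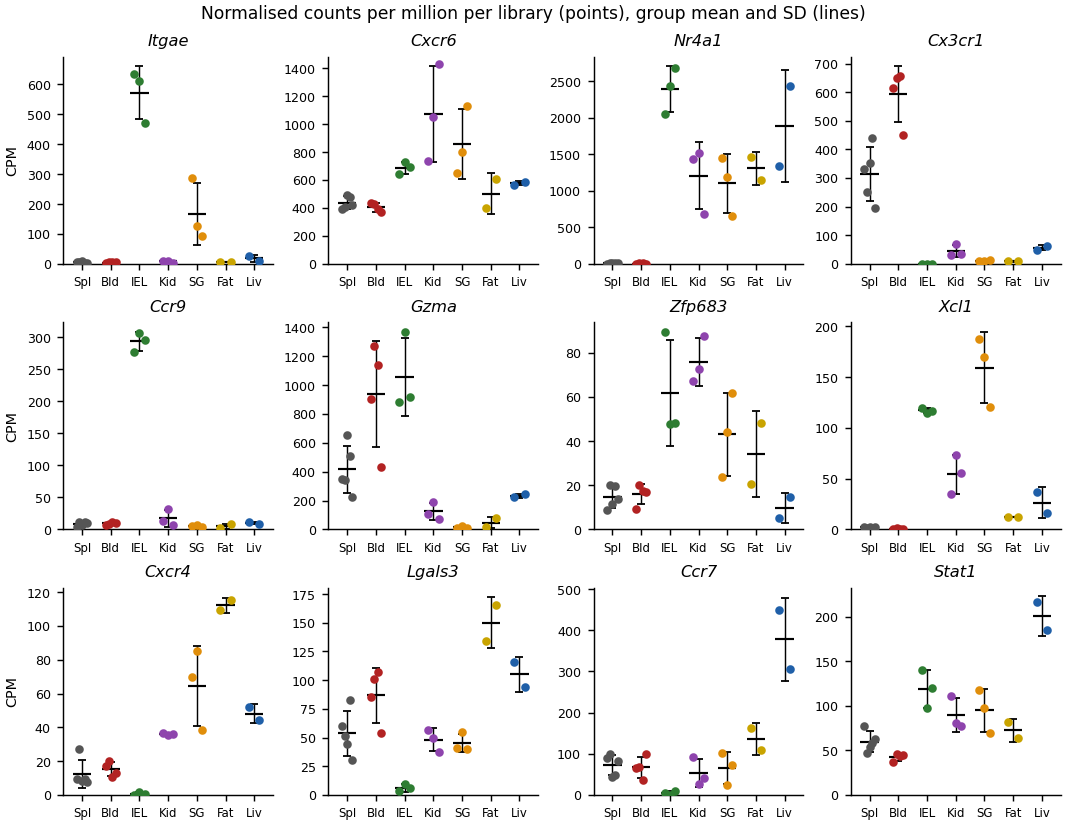
Points are the CPM of each library by site (horizontal axis) for 12 genes, with lines for the group mean and SD, on linear axes from 0. The 12 genes were picked for the plot after their values were seen; Itgae is at 572 ± 87.5 CPM in IEL and 168 ± 104 in salivary gland, and Ccr9 at 293 ± 14.8 in IEL.

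The remaining comparisons set each tissue against the mean of the other 4, which tests its distance from that mean. A gene can pass because some of the other tissues are extreme, so a call does not by itself set the tissue apart from each of them. IEL were incubated without collagenase and the other 4 tissues with it. For all calls of IEL against other tissues, digestion and tissue of origin therefore cannot be told apart. For each gene given here with a log2 fold change, all libraries of the tissue lay on one side of the median of each other tissue unless said otherwise. In IEL, Ccr9 was at 293 against 9.51 CPM (log2 fold change 5.06 (SE 0.267), adjusted p = 8.69e-14) and Itgae at 572 against 50.4 (4.82 (SE 0.26), adjusted p = 1.13e-13). Gzma had 1060 ± 271 CPM in IEL against 105 elsewhere (3.96 (SE 0.293), adjusted p = 7.17e-11). The inhibitory receptor genes Lag3 (3.20) and Cd160 (2.51) were also higher. Ly6c2, which encodes a form of the surface antigen Ly6C, was at 22.6 ± 6.88 CPM against 1190 (-5.60 (SE 0.188), adjusted p = 4.39e-18; ENSMUSG00000022584.14, chromosome 15, 75108158 to 75111970). Cxcr4 (-6.46, or -8.12 without IEL 2), the galectin gene Lgals1 (-4.97), S1pr1 (-4.70) and the transcription factor gene Eomes (-2.91) were lower as well.

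Of the 24 cholesterol genes, 20 were higher and 1 lower (camera adjusted p = 1.37e-22) in IEL against other tissues. Of the 18 glycolysis genes, 0 were higher and 11 lower (median log2 fold change -0.55, camera adjusted p = 3.61e-08), with Tpi1 at -0.87. Of the 26 residency-associated genes, 18 were higher and 0 lower (camera adjusted p = 4.58e-24). Of the 22 circulation-associated genes, 1 was higher and 16 lower (camera adjusted p = 5.72e-13). Of the 14 inhibitory receptor genes, 11 were higher and 1 lower (camera adjusted p = 1e-12). Of the 11 TGF-beta response genes, 6 were higher and 0 lower (camera adjusted p = 1.17e-08). Of the 22 trafficking genes, 3 were higher and 11 lower (camera adjusted p = 0.000471). Of the 5 gut epithelium markers, 2 were higher and 0 lower (camera adjusted p = 0.00149). For IEL, counts adjusted over the list alone were the same except 22 and 1 for cholesterol genes, 0 and 13 for glycolysis, 20 and 1 for residency, 1 and 17 for circulation, 7 and 0 for the TGF-beta response, 3 and 14 for trafficking and 4 and 0 for gut epithelium. IEL had 665 genes higher and 681 lower, 1346 in all, which became 879 without IEL 1 and 828 without IEL 2.

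Kidney had the fewest genes apart from the other tissues, 89 higher and 26 lower. Kcnj8, a subunit of a potassium channel, was at 30.6 ± 3.68 CPM against 10.2 (log2 fold change 1.70 (SE 0.209), adjusted p = 2.37e-05; ENSMUSG00000030247.9, chromosome 6, 142564837 to 142571614). Cx3cr1 changed by 2.36 and Ccl3 by 1.58. Itgae was at 7.97 against 192 CPM (-3.01 (SE 0.396), adjusted p = 5.62e-05) and the ectoenzyme gene Nt5e (CD73) changed by -1.82. The kidney libraries did not lie on one side of every other tissue's median for Cx3cr1, Ccl3 and Itgae. Zfp683, which encodes the residency factor Hobit, was at 75.9 ± 10.7 against 37.3 CPM (1.31 (SE 0.282), adjusted p = 0.0211; ENSMUSG00000049410.8, chromosome 4, 134053838 to 134058996), a call that ended without kidney 2 (adjusted p = 0.0932) or kidney 3 (0.212). Of the 22 circulation-associated genes, 6 were higher and 0 lower (camera adjusted p = 1.33e-05). Of the 11 TGF-beta response genes, 0 were higher and 3 lower (median log2 fold change -0.77, camera adjusted p = 6.59e-07). Of the 24 cholesterol genes, 0 were higher and 1 lower (camera adjusted p = 1.33e-06). Of the 7 B cell markers, 4 were higher and 0 lower (camera adjusted p = 8.47e-05, but adjusted p = 0.0834 with an estimated correlation), and Cd74 no longer passed without kidney 3 (adjusted p = 0.53). For kidney, counts adjusted over the list alone were the same except 9 and 1 for circulation, 0 and 5 for the TGF-beta response, 0 and 7 for cholesterol genes and 5 and 0 for B cell markers. The count of 115 was 32 without kidney 2, 30 without kidney 3, 60 without fat 1, 176 without salivary gland 3 and 175 without liver 2. It was 174 with DESeq2, 177 with limma voom, 200 without a filter, 65 with the replicate block and 61 without fat 1 and salivary gland 2.

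In salivary gland, Spsb1, an adaptor of a ubiquitin ligase, was at 173 against 25.6 CPM (log2 fold change 3.58 (SE 0.229), adjusted p = 6.02e-11). Krt83 changed by 3.52 (4.19 without IEL 3), Cdh1 by 3.44 (adjusted p = 8.47e-09; 5.22 without fat 2) and Xcl1 by 2.06. Gzma was at 14.6 against 366 CPM (-3.84 (SE 0.437), adjusted p = 1.81e-06). Gzmb changed by -1.80, Klrb1c by -3.10 and Lag3 by -2.82 (-3.58 without salivary gland 1). Of the 11 TGF-beta response genes, 8 were higher and 0 lower (median log2 fold change 1.43, camera adjusted p = 1.2e-18). Of the 26 residency-associated genes, 12 were higher and 1 lower (camera adjusted p = 4.05e-15). Of the 20 cytotoxic effector genes, 1 was higher and 6 lower (median log2 fold change -0.33, camera adjusted p = 1.34e-07, but adjusted p = 0.0574 with an estimated correlation). Of the 7 B cell markers, 4 were higher and 0 lower (camera adjusted p = 0.00264, but adjusted p = 0.175 with an estimated correlation), and Cd74 no longer passed without salivary gland 3 (adjusted p = 0.212). For salivary gland, counts adjusted over the list alone were the same except 14 and 2 for residency, 2 and 9 for cytotoxic effectors and 5 and 0 for B cell markers. Salivary gland had 220 genes higher and 75 lower, 295 in all, against 136 without salivary gland 1, 180 without salivary gland 2 and 183 without it and fat 1.

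Fat had 115 genes higher and 113 lower than the other tissues. Lmna, which encodes lamin A, was at 176 ± 42.9 CPM against 35.5 (log2 fold change 2.92 (SE 0.33), adjusted p = 2.16e-06). Ly6c2 was at 1830 ± 29.3 CPM against 742 (2.29 (SE 0.129), adjusted p = 2.5e-12), Cxcr4 changed by 2.76 and the galectin gene Lgals3 by 2.13. Itgae was at 6.44 against 192 CPM (log2 fold change -3.21), a call that ended without fat 2 (adjusted p = 0.0555). Xcl1 (-2.56), Ccl3 (-2.48) and Dtx1 (-3.19) were lower. Of the 26 residency-associated genes, 0 were higher and 9 lower (median log2 fold change -0.87, camera adjusted p = 4.43e-15). Of the 19 interferon-stimulated genes, 0 were higher and 2 lower (median log2 fold change -0.71, camera adjusted p = 8.14e-09). Of the 22 circulation-associated genes, 4 were higher and 0 lower (camera adjusted p = 5.5e-07). For fat, counts adjusted over the list alone were the same except 2 and 15 for residency, 0 and 11 for interferon-stimulated genes and 6 and 0 for circulation. The count of 228 was 120 without fat 1, 103 without fat 2 and 113 without fat 1 and salivary gland 2.

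Liver had 526 genes higher and 237 lower than the other tissues. Genes of recirculating cells were among the higher ones. Ccr7 was at 378 CPM against 65.1 (log2 fold change 3.25 (SE 0.34), adjusted p = 2.35e-07). The transcription factor genes Tcf7 and Klf2, the latter a driver of S1pr1, changed by 1.52 and 1.89. Cxcl10 was at 116 against 9.97 CPM (3.74 (SE 0.306), adjusted p = 1.36e-08). Ifng changed by 1.91, Il2ra by 1.97 and Hk2 by 2.31. The ATP receptor gene P2rx7 (-2.11) and Chn2 (-2.77, or -3.40 without liver 1) were lower. Zfp683 was at 9.84 against 53.8 CPM (-2.49), with -3.31 without liver 2 and a call that ended without liver 1 (-1.83, adjusted p = 0.06). Of 22 circulation-associated genes, 16 were higher and 0 lower (camera adjusted p = 1.13e-17). Of the 18 glycolysis genes, 11 were higher and 0 lower (median log2 fold change 0.72, camera adjusted p = 1.11e-16). Of the 19 interferon-stimulated genes, 15 were higher and 0 lower (median log2 fold change 1.14, camera adjusted p = 9.2e-23). Of 26 residency-associated genes, 1 was higher and 12 lower (camera adjusted p = 7.12e-07). For liver, counts adjusted over the list alone were the same except 17 and 0 for circulation, 12 and 0 for glycolysis, 18 and 0 for interferon-stimulated genes and 1 and 14 for residency. The count of 763 was 257 without liver 1 and 356 without the second plate.

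Markers of other cells stayed low beside those of CD8+ T cells, whose 10 genes summed to 5540 ± 155 CPM in spleen, 6980 ± 474 in IEL and 6830 ± 723 in liver. Fibroblast, endothelium, erythroid and platelet, kidney epithelium and adipocyte markers summed to at most 7.57 CPM in each group, although salivary gland 2 alone held 18.5 CPM of adipocyte and 15.4 CPM of erythroid and platelet markers. These 5 lists and hepatocyte markers had fewer than 3 tested members and no list test. B cell marker sums were 96.6 ± 21.9 CPM in spleen, 220 ± 118 in kidney and 235 ± 148 in salivary gland. CD4 T cell marker sums were 33 ± 8.31 CPM in spleen and 197 ± 15.1 in liver (camera adjusted p = 0.0169, but adjusted p = 0.114 with an estimated correlation), mainly from Il2ra, which activated CD8+ T cells express too. The sex-linked list, in which Xist and the Y-linked genes follow the plate as given above, passed in blood against spleen (camera adjusted p = 0.00529, but adjusted p = 0.136 with an estimated correlation, 0.913 with the replicate block, 0.55 with the run of wells and 0.637 with the plate in the fit).

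**Figure D5:**
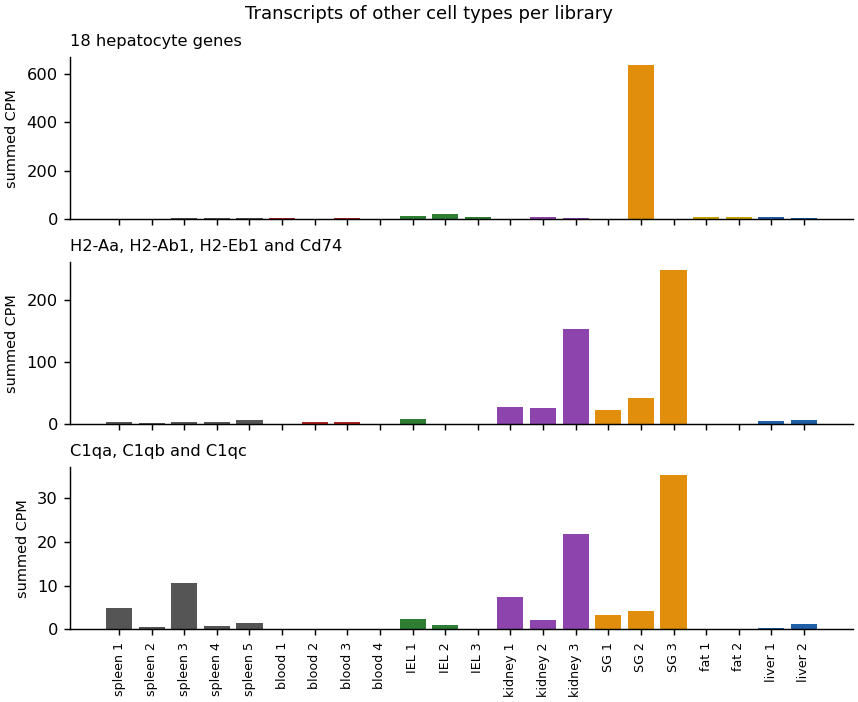
Bars give summed CPM per library (vertical axes) of 18 hepatocyte genes, of 4 MHC class II genes and of 3 complement C1q genes, for the 22 libraries (horizontal axis). The hepatocyte sum is 636.6 CPM in salivary gland 2, and the class II sum is 153.8 CPM in kidney 3 and 248.2 in salivary gland 3.

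The transgenic receptor uses an alpha-chain segment of the Trav14 family, whose members are close paralogs, so their counts are uncertain. The Trav14-1 share of all Trav counts was 93.1% ± 1.5 (SD) over the 13 tissue libraries and 86.4% ± 1.8 over the 9 spleen and blood libraries, a difference of 6.7 percentage points. The exact two-sided permutation test gave p = 2e-06, the smallest the 497420 splits allow, and the lowest tissue library (90.95%) lay above the highest from spleen or blood (88.16%). The test moves single libraries freely between sites. Its p-value therefore treats libraries of a site as independent and does not measure the spread between sites. On the second plate alone the shares were 85.67% in spleen 1, 91.75% in salivary gland 1 and 95.24% in liver 1. The share of the beta-chain segment Trbv13-3 among all Trbv counts overlapped, at 57.73% to 89.78% in tissue libraries and 43.53% to 79.74% in spleen and blood. It was lowest of each group in spleen 3 (55.49%), blood 2 (43.53%), IEL 2 (57.73%) and kidney 2 (62.59%), the 4 libraries of a shared run of wells.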

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

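The tests of the 3 patterns weighed below were chosen only after the results were seen, while the other splits of the libraries were planned. Groups of 4 to 10 libraries, spleen and blood here, were searched for a library far from the rest on 39 measures, 78 searches in all, of which 2 gave a hit; chance gives about 1 in 20. Spleen 3 had 17606 detected features against 21008 in the next lowest spleen library. Blood 4 had a mean log2 CPM of immediate-early and heat-shock genes of 3.732 against 3.537 in the next blood library.

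The difference of each tissue's change from that of the other tissues was itself tested: 1346 genes for IEL, 115 for kidney, 295 for salivary gland, 228 for fat and 763 for liver. Other splits of the same libraries into groups of the same sizes show how often other labels reach the real count. Against spleen, 1 of 56 splits gave as many genes as the real one for IEL (2682, highest other 331), for kidney (1181, highest other 99) and for salivary gland (2070, highest other 185). A share of 1 in 56 is the smallest possible there and was not adjusted over the comparisons, so chance is not excluded by it. Fat and liver had no split test of their own. For tissues against circulation, 1 of 100 drawn splits reached 4031, with 367 as the highest other. For IEL against other tissues, 1 of 100 reached 1346, with 115 as the highest other. For blood against spleen, 2 of 100 drawn splits reached 5; the highest other, 6, set spleen 1 with the blood libraries against spleen 2 to 5 and so parts off the spleen library of the second plate, and without that plate the real split gave 21. For kidney against other tissues, 4 of 100 reached 115 and the highest other was 1002, from the split that put the kidney label on the IEL libraries, a count that reflects the structure of the samples. For salivary gland against other tissues, 3 of 100 reached 295, and the highest other, 323, had fat 1 and both liver libraries under the salivary gland label.

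Immediate-early and heat-shock genes had a median log2 fold change against spleen of 2.75 or more in each tissue and of -0.49 in blood (-0.425 with low-count genes at their bounds). Collagenase as the whole cause is argued against by IEL, which saw no collagenase and had a median of 3.33. Plate or run of wells is argued against too, since the smallest tissue median was 2.8 with either in the fit. Incubation at 37 degrees cannot be told apart from tissue of origin, because all 5 tissues and neither reference were incubated: the smallest median over the incubated tissues was 2.75. A biological difference between tissue and circulating cells stays open as well, untested.

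Salivary gland 2 held transcripts known from hepatocytes: 16 of 18 listed hepatocyte genes were above 3 times the highest other library plus 1 CPM, led by Alb (195.4 CPM), Ttr (87.9) and Trf (58.8). RNA or cells from liver in this library cannot be told apart from other sources by that count, which restates the finding itself. The 18 genes summed to 11.4 CPM in liver 1 and to 4.4 CPM in liver 2, the latter from the same run of wells. Those low sums argue against carry-over from these liver libraries as the source. A liver library under a wrong label is argued against, because its mean correlation with the other salivary gland libraries was 0.129 above that with the liver libraries. Salivary epithelium as the source is argued against by its own markers, which summed to 37.6 CPM, above the 14.4 CPM of the next library but beside 636.6 CPM of hepatocyte genes. No biological explanation was tested.

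MHC class II transcripts were higher in the 6 kidney and salivary gland libraries than in the other 16, with most in kidney 3 (153.8 CPM) and salivary gland 3 (248.2 CPM). Both came from the same run of wells, in which spleen 5 held 7.5 CPM, blood 4 0.9, IEL 3 1.2 and fat 2 1.4. Cd79a, Cd79b and Ms4a1 summed to at most 2.1 CPM in kidney 3 and salivary gland 3, under the median of 5.2 elsewhere, which argues against B cells by those genes. The full B cell list, class II genes included, summed to 354.9 CPM in kidney 3 and 404.9 in salivary gland 3. In IEL 3, the highest of the other 16 libraries, it was 155.4, with a class II sum of 1.2. Members of the list outside class II were thus no lower in kidney 3 and salivary gland 3, and B cells are not excluded in those 2 libraries. Macrophages or dendritic cells are a candidate source for those 2 libraries, as the C1q genes reached 21.8 CPM in kidney 3 and 35.2 in salivary gland 3 against at most 10.6 in the others, although the sort was set on P14 cells. For the other 4 kidney and salivary gland libraries such cells cannot be told apart from expression by the T cells, with the lowest C1q sum at 2.2 CPM, within the range of the remaining libraries, and Ciita, the class II transactivator, at 0 to 2.6 CPM against at most 4.1 CPM there, too few counts to decide. A difference between tissues stays open, untested.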

How the results depend on the processing

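Leaving out fat 1 with salivary gland 2, and leaving out the 5 features with most counts, were chosen after seeing the data; other settings were planned, and the cause of a change was not tested unless its construction shows it. Under DESeq2 size factors, the stricter filter and the removal of the 5 features, all 14 gene counts stayed within 1.5 times, and no scaling moved the median of all genes by 0.1 on the log2 scale. Blood against spleen (5 genes) gave 44 with the DESeq2 Wald test, 12 with voom, 78 without a filter, 41 with the run of wells and 16 with the plate in the fit, 21 without the second plate, 16 in a fit of 2 groups and 11 without fat 1 and salivary gland 2. Kidney against other tissues (115) gave 174 with the Wald test, 177 with voom, 200 without a filter and 61 without fat 1 and salivary gland 2. With the fewer libraries left by dropping the second plate, liver against spleen gave 827 genes, liver against other tissues 356 and the shared lower genes 53. Without fat 1 and salivary gland 2, fat against spleen gave 610 genes, salivary gland against other tissues 183, fat against other tissues 113 and the shared lower genes 54. With voom the calls in fat split 866 higher to 310 lower against spleen (73.6% higher, main 62.7%) and 157 to 77 against other tissues (67.1%, main 50.4%).

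Requiring an absolute log2 fold change of at least 1, which can only lower a count, left 1712 genes for IEL, 779 for kidney, 1293 for salivary gland and 1069 for liver against spleen, 1586 for tissues against circulation, 697 for IEL, 69 for kidney, 170 for salivary gland, 147 for fat and 409 for liver against other tissues, and 56 shared lower genes. With blood as the control, the counts were 2499 in IEL, 1215 in kidney, 2203 in salivary gland, 1285 in fat and 1865 in liver.

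The replicate numbers gave no sign of pairing the libraries. Deviations of same-numbered libraries had a median correlation of -0.00467 over 53 pairs (-0.182 to 0.439, 6 above 0.1). Of 22 libraries, 8 correlated best with their own number. Spleen 1 and blood 1 share a number but held 369.83 and 3.68 CPM of Xist. Deviations were taken from the site mean, so those of fat 1 and fat 2, or of liver 1 and liver 2, mirror each other. The correlations here and for runs of wells are therefore not independent of each other. Libraries of the same run of wells shared more: a median of 0.0377 over 40 pairs, 11 above 0.1, against -0.0105 over 164 pairs from different runs, 6 above 0.1; the 3 pairs on the second plate lay at 0.298 to 0.438, and 12 of 22 libraries correlated best with their own run. With the run of wells in the fit, no gene count but that of blood moved by over 1.5 times (IEL 2767, kidney 1290, salivary gland 2185, fat 1456 and liver 1669 against spleen). The replicate block gave 65 genes for kidney against other tissues and moved no other gene count by over 1.5 times (4 in blood, 2277 in IEL, 930 in kidney, 1646 in salivary gland, 1056 in fat and 1187 in liver against spleen). It called 144 list tests, 130 of them among the 135; the run of wells called 136, 123 of them among the 135, the plate 140 (129 among them), with each lost call that the text gives named beside its list, and the estimated correlation called 57.

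With each library left out in turn, the counts ranged from 4 to 18 for blood, 606 (without fat 1) to 1399 for fat and 809 (without liver 1) to 1712 for liver against spleen. Against other tissues they ranged from 828 (without IEL 2; 879 without IEL 1) to 1553 for IEL, 30 to 176 for kidney, 136 to 330 for salivary gland, 103 to 291 for fat and 257 (without liver 1) to 1031 for liver. The blood count moved without spleen 1 (11), spleen 4 (8), blood 4 (18) and salivary gland 2 (11). The kidney count moved without kidney 2 (32), kidney 3 (30), fat 1 (60), salivary gland 3 (176) and liver 2 (175). The salivary gland count moved without salivary gland 1 (136) and 2 (180), and the fat count without fat 1 (120) and 2 (103). Shared lower genes ranged from 50 (without fat 1; 61 without liver 1) to 98. Where a site keeps 1 library, that library is assumed to vary like the other groups.

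Of 23989 values of named genes under alternatives, 1099 lost the call and 11 changed direction. Without salivary gland 2 and fat 1, Fabp1 went to -1.33 (adjusted p = 0.689) and Apoa1 to -2.87 against spleen, and to -2.21 and -2.36 against other tissues. Over single libraries left out, Fabp1 ranged from -1.29 (without salivary gland 2) to 8.53 against spleen and from -2.18 to 6.98 against other tissues. Xist, which follows the plate, went to -1.24 without the second plate for salivary gland against other tissues, with a range of -2.66 (without salivary gland 1) to 6.80 over single libraries. For liver it went to -0.51 with the run of wells and -0.24 with the plate in the fit, with a range of -0.96 (without liver 1) to 6.99. The sex-linked list in blood, as signed -log10 adjusted p, went from 2.28 to -0.04 with the replicate block and -0.26 with the run of wells. In fat, with 2 libraries and the lowest depth in fat 1, 20% of simulated 2-fold changes were recovered; depth and number of libraries were not told apart.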

Other observations

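Among the tissues, Tnfrsf25, which encodes a costimulatory receptor of the TNF receptor family, was highest in liver and lowest in IEL. It was at 86.8 ± 21.2 CPM in liver, and the difference from the other tissues passed the test (adjusted p = 1.85e-15). In IEL it had 1 count over the 3 libraries. The spleen libraries held 59.66 to 75.04 CPM, nearer to liver than to the other tissues. The kidney libraries held 15.83 to 19.76, the salivary gland libraries 6.88 to 7.66 and the fat libraries 12 and 15.47.

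Cd40lg, which encodes the ligand of CD40 and is best known from CD4 T cells, was at 25.4 CPM in tissues and 3.79 in circulation (log2 fold change 2.65 (SE 0.308), adjusted p = 9.12e-08). Il2ra was at 68.4 against 17.4 CPM there (1.64 (SE 0.161), adjusted p = 3.88e-09). Counts of the gamma-delta constant segments Trgc1 and Trgc2, which have close paralogs and are uncertain, were highest in IEL, with Trgc2 at 22.4, 50.92 and 16.72 CPM against at most 11.15 CPM in each other library. The sum of all listed gamma-delta T cell markers was not highest there. It was 190 ± 27.1 CPM in IEL, 204 ± 47.3 in kidney and 164 ± 34.8 in spleen.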
